A study of Homo sapiens with 6 samples.

How the data were processed

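CUT&RUN libraries were made from K562 cells with antibodies to ERH and WBP11 diluted 1:50 and with rabbit IgG, 2 samples each, per the labels. The submitters' processing notes name Trim Galore 0.4.5, Bowtie2 2.2.9, Picard 2.8.0, MACS2 2.1.1 and the human build hg38; per the series' design text, peaks were called relative to IgG. The parameters of these tools, any selection by fragment length, the treatment of duplicates and any spike-in scaling are not given in the sources used here. These steps can change which peaks are listed: short fragments sharpen peaks of factors that touch DNA directly, duplicate removal lowers strong peaks, and weak IgG signal raises fold enrichment.

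Each antibody has 2 deposited peak lists in the narrowPeak layout, with coordinates on hg38, which were converted here to 1-based positions. The score in the deposited lists is a display score equal to 10 times the −log10 q, rounded down, and was not used further. The fold enrichment deposited by the authors is a linear ratio at the summit, of signal over the background that MACS2 estimates with the control. Unrelated regions can share 1 value, such as 14.6 for WBP11 at CDCA3, MRPS28 and EIF2AK3. The ratio therefore need not reflect IgG signal at each place. The −log10 p and −log10 q values deposited by the authors give the significance of each summit, and the lowest −log10 q in the lists is 2.02. The position of the summit within its peak was taken from the deposited lists as well. Peak names carry a mark of combined alignments, and the 2 lists of an antibody hold the same entries, so the lists were read as peaks called per antibody on pooled samples. The lists hold no read totals: depth is unknown, no value carries a replicate error, and intervals cover counting of regions or genes only. Peaks on chromosomes 1 to 22 were present in the lists and used; chromosome X was not analysed here. IgG was not analysed here.

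Several summits can share a peak interval, so each interval was counted once, as a region with its strongest summit (2382 summits in 2037 regions for ERH, 2193 in 2018 for WBP11). Gene positions came from a RefSeq gene table of assembly GRCh38.p14, the same build, with 19126 protein-coding genes and 56756 annotated genes on chromosomes 1 to 22. This table gives the start and end of each gene but no strand, exon or sequence. The plan fixed before the data were examined used transcription start sites; either annotated end of a protein-coding gene took their place, and summits within 1000 bp of one were called gene-end regions. Assembly gaps were replaced by stretches over 1 Mb without an annotated gene. Whether a summit lies in an exon, an intron or an untranslated region was not determined. The planned tests that need strand, exons or sequence were not run: 14 motifs at summits, CpG-rich promoters, exon boundaries, soft-masked repeats and promoters with an opposite start.

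Shares carry exact Clopper-Pearson 95% intervals. Regions were placed at random on the same chromosome 1000 times (200 times for alternatives), which gives one-sided p-values of at least 0.000999. Regions overlapped if they shared at least 1 bp. Genes and gene lists were compared by two-sided Fisher's exact tests, with Benjamini-Hochberg adjustment over 40 tests of 20 lists, 20 tests between antibodies, 44 tests of 22 chromosomes and 22 tests of chromosomes between antibodies, and a threshold of 0.05. A gene had a peak if a summit lay within 1000 bp of either end, so 1 region can mark 2 neighbouring genes. Medians of fold enrichment were compared within a list by permutation with 100000 resamples (10000 for alternatives). The 20 gene lists, the tests and the first set of alternatives were chosen before the data were examined. The lists were also set against 10000 random lists matched on deciles of gene density within 100 kb, except the small nuclear and small nucleolar lists. The overlap of ERH regions at histone genes with WBP11 was set against 10000 draws of other gene-end regions from the same deciles of −log10 q. Odds ratios within strata were pooled by the Mantel-Haenszel method.

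The genes named in the text followed a rule fixed before the data were examined. For each antibody it takes the 12 gene-end regions and the 5 regions away from gene ends with the highest −log10 q. It then takes the 8 shared regions with the best worse-rank, the 6 strongest gene-end regions found in a single list, up to 4 members of each gene list by highest fold enrichment, the genes for ERH and WBP11, and every chromosome past its test. An item that this rule takes is not reported here.

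The computations used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9. The gene list test was tested on simulated data: over 20 simulated pairs of lists on the 19126 genes, 3 lists given an odds ratio of 5 returned a median of 5.02 and were called in 86.7% of cases, and unchanged lists were called in 0.405%. For the overlap, 30% of the regions of 1 simulated list were copied into the other, and 30.04% were returned. This checks the counting only, not whether random placement suits real peaks. Simulated peaks fell at 1 rate on all genes not given the odds ratio. The call rate of unchanged lists therefore does not cover a background with silent genes. Alternatives covered stricter thresholds, equal list lengths, other windows, other definitions of overlap, other random placements and the counting of every summit.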

Results

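CUT&RUN maps where a chromatin protein sits by letting an antibody guide a nuclease, which releases the DNA fragments around the bound protein for sequencing. It was applied here to K562, an established human line from chronic myeloid leukaemia, with antibodies against ERH and WBP11 and with rabbit IgG as the control. ERH is a small conserved nuclear protein, and WBP11 is a nuclear protein that binds WW domains; both have been linked to pre-mRNA splicing. The series describes them as proteins newly found at open chromatin, and the comparisons it implies are each antibody against IgG and the ERH peaks against the WBP11 peaks. There were 6 samples, 2 per antibody and 2 for IgG, each assay starting from 500000 cells. The 2 replicate lists of each antibody were identical in every entry (2382 of 2382 for ERH and 2193 of 2193 for WBP11). This points to 1 call on pooled reads for both samples and says nothing on agreement between cultures, so they were counted as 1 list. No spread between replicates could be computed, and every p-value below describes the positions within these lists, not a difference between cultures. Read totals do not stand in the lists, so the depth behind them is unknown; IgG enters only as the control the authors called peaks against, and its own signal was not analysed here.

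ERH had its peaks mainly just outside gene ends, and its strongest regions there included genes of DNA replication (TICRR, CHAF1A) and protein folding (SDF2L1). Its strongest region lay on chromosome 15 at 89575239 to 89575532, 138 bp outside TICRR, a gene for a replication initiation factor, with a fold enrichment of 64.2 and a −log10 q of 228. Of the 2037 ERH regions, 1346 (66.1%, exact 95% interval 64.0 to 68.1) had their summit within 1000 bp of an end of a protein-coding gene, against a mean of 3.88% when the regions were placed at random on the same chromosomes (one-sided p = 0.000999, the smallest that 1000 placements can give). The median fold enrichment was 10.1, with quartiles of 6.78 and 16.0, and the median width of a region was 152 bp.

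The other strongest ERH regions at gene ends covered several kinds of gene. After TICRR came ABCB8, a mitochondrial transporter, on chromosome 7 at 151028189 to 151028459 (fold enrichment 59.3), and MYL11, a muscle myosin light chain, on chromosome 16 at 30370554 to 30371227 (fold enrichment 50.8). CAMTA1, a calmodulin-binding transcription activator, had a region on chromosome 1 at 6784980 to 6785391, whose summit was nearer to the divergent non-coding gene CAMTA1-DT (176 bp) than to CAMTA1 itself (298 bp). CHAF1A, the large subunit of chromatin assembly factor 1, carried a region of fold enrichment 68.5 on chromosome 19 at 4402288 to 4402560. TOP2A, a DNA topoisomerase of dividing cells, had a region of fold enrichment 51.3, and PRR11 had a region of fold enrichment 46.1. STIP1, a co-chaperone of HSP70 and HSP90, carried a region whose summit lay 617 bp inside the gene (fold enrichment 53.5). EIF2AK3, the kinase PERK of the unfolded protein response, had its summit 360 bp inside the gene on chromosome 2 at 88627465 to 88627893, with a fold enrichment of 64.8. SDF2L1, a protein of the endoplasmic reticulum, had a region of fold enrichment 34.1 on chromosome 22 at 21642033 to 21642305. MTMR4, a lipid phosphatase, had a region of fold enrichment 47.5 with its summit 902 bp inside the gene.

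Away from gene ends, 306 ERH regions (15.0%) lay inside a protein-coding gene, against 44.5% of random placements, and 218 (10.7%) lay elsewhere, against 47.1% (one-sided p for a lower share of 0.000999 in both, the smallest possible). The remaining 167 regions (8.20%) were at an end of another annotated gene only. The strongest of the regions away from protein-coding gene ends was 2078 bp outside ZBTB32, a zinc finger repressor, on chromosome 19 at 35702405 to 35702627, with a fold enrichment of 70.9. Others lay 1503 bp inside HNRNPUL1 (fold enrichment 43.6), 2080 bp outside GREP1 (fold enrichment 58.5) and 1025 bp inside ABCA7 (fold enrichment 55.5). A region on chromosome 7 at 25862138 to 25862589 had NFE2L3, at 289797 bp, as its nearest protein-coding gene.

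WBP11 peaks were likewise placed mainly at gene ends, and among the regions there DCAF7, INTS7, LOC124903090 and TUBB had the strongest. The strongest region lay 198 bp outside DCAF7, an adaptor of an E3 ubiquitin ligase, on chromosome 17 at 63550209 to 63550497, with a fold enrichment of 23.4 and a −log10 q of 41.1. Of the 2018 WBP11 regions, 1256 (62.2%, exact 95% interval 60.1 to 64.4) had their summit within 1000 bp of a protein-coding gene end, against a mean of 3.17% in random placements (one-sided p = 0.000999, the smallest possible). The median fold enrichment was 6.14, with quartiles of 5.03 and 7.64, and the median width was 129 bp. Fold enrichments rank regions within 1 list and were not compared between the antibodies.

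INTS7, a subunit of the Integrator complex that processes small nuclear RNAs, had a WBP11 region 467 bp inside the gene on chromosome 1 at 212035043 to 212035264 (fold enrichment 17.7). PHF5A, a component of the SF3B splicing complex, had its summit 18 bp outside the gene on chromosome 22 at 41468661 to 41468765 (fold enrichment 15.2). RBM15, an RNA-binding protein, carried a region of fold enrichment 11.9 on chromosome 1 at 110339099 to 110339429, and DDX59, an RNA helicase, a region of fold enrichment 13.1. TUBB, a beta-tubulin, had a region of fold enrichment 15.9, and CDCA3, a regulator of entry into mitosis, a region of fold enrichment 14.6. STT3A, a catalytic subunit of the enzyme that glycosylates proteins in the endoplasmic reticulum, had a region of fold enrichment 13.5, with its summit 164 bp from the antisense gene STT3A-AS1. SDF2L1 appeared here too, with a fold enrichment of 10.2. GTPBP1 (fold enrichment 16.0), RBBP5 of the histone methyltransferase complexes (fold enrichment 10.3) and the uncharacterised gene LOC124903090 (fold enrichment 15.8) were the rest of the 12 strongest at gene ends.

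Among WBP11 regions, 398 (19.7%) lay inside a protein-coding gene away from gene ends, against 43.5% of random placements, and 239 (11.8%) lay elsewhere, against 49.0% (one-sided p for a lower share of 0.000999 in both). Another 125 (6.19%) were at an end of another annotated gene only. The strongest of those away from protein-coding gene ends, on chromosome 1 at 143214702 to 143214782, was 687645 bp from the nearest protein-coding gene, H3-7, and had a fold enrichment of 10.8. The next were inside HCN2 (fold enrichment 19.5), KCNK1 (fold enrichment 13.3), NPAS4 and FAM117A (fold enrichment 16.3), with summits 12571, 22020, 4963 and 29710 bp from the nearer end of the gene. Among these the chromosome 1 region far from genes had the highest −log10 q (38.3) with the lowest fold enrichment. No filter for repeated or high-signal stretches was applied here, so that region may be an artefact.

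Summits of both lists lay mainly on the outer side of gene ends. IgG summits were not analysed here, so cutting of open chromatin by any antibody was not separated from the position of the proteins. Of the summits at gene ends, 86.6% for ERH (1165 of 1346, exact 95% interval 84.6 to 88.3) and 84.0% for WBP11 (1055 of 1256, interval 81.9 to 86.0) lay outside the gene (two-sided exact binomial p = 2.99e-176 and 4.40e-140 against 50%). The median position, negative outside the gene, was −92 bp for ERH and −99.5 bp for WBP11, and 85.9% and 85.1% of the summits were within 300 bp of the end. The annotation at hand gives no strand, so the start of a gene was told from its finish only at 518 genes with a named divergent transcript, which begins near the start of its partner and runs the other way. At these genes 68 carried an ERH peak at the end that faces the divergent transcript and 2 at the opposite end (exact McNemar p = 4.68e-19). For WBP11 the counts were 62 and 0 (exact McNemar p = 4.34e-19).

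**Figure D1:**
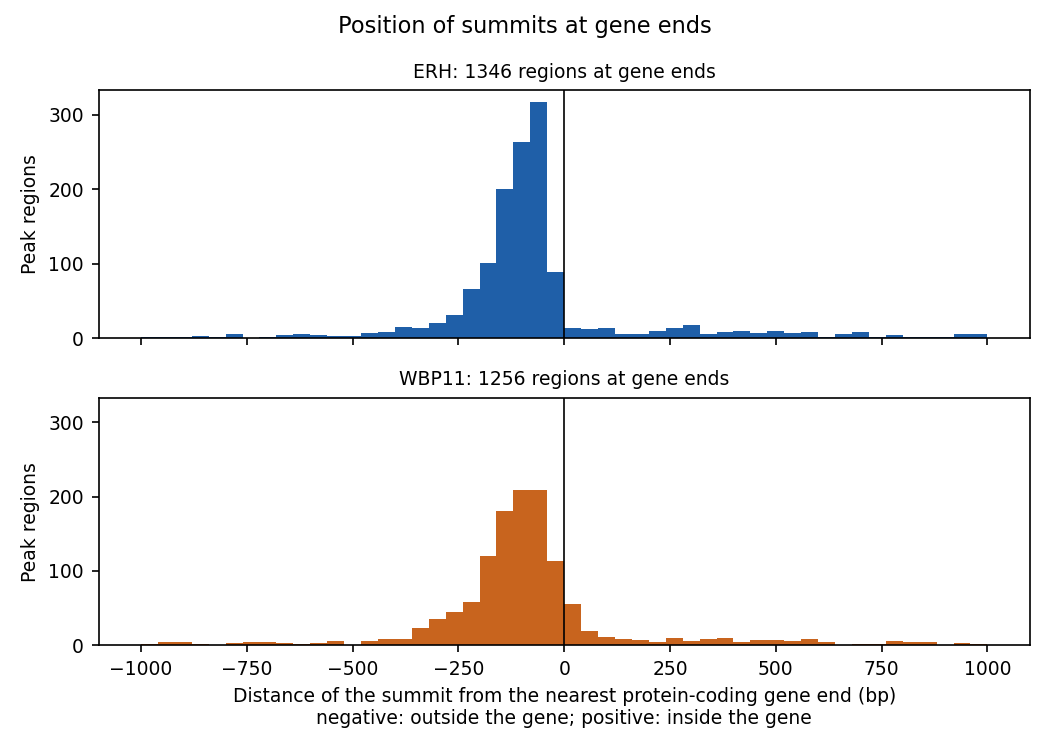
Number of peak regions (vertical axis) by the distance in bp of their summit from the nearest protein-coding gene end (horizontal axis, negative outside the gene), for the 1346 ERH and the 1256 WBP11 regions at gene ends in bins of equal width. Both distributions peak on the outer side of the end, with medians of −92 bp and −99.5 bp.

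ERH and WBP11 peaks met at many of the same places, among them the ends of SDF2L1, EIF2AK3, MYL11, RBM15, KHSRP, OS9, RPS6KA5 and SP1. Of the ERH regions, 669 of 2037 (32.8%, exact 95% interval 30.8 to 34.9) overlapped a WBP11 region by at least 1 bp, and 684 of 2018 WBP11 regions (33.9%, interval 31.8 to 36.0) overlapped an ERH region. Random placement of the WBP11 regions on the same chromosomes gave a mean of 0.0390% of ERH regions, and placement of those at gene ends onto the ends of random genes gave 1.62%, with a highest value of 2.41% (one-sided permutation p = 0.000999 for each, the smallest possible). The random genes were drawn from all protein-coding genes, silent ones included, and either end was equally likely. Peaks at genes with a named divergent transcript lay almost only at the end facing it. The mean of 1.62% may therefore be too low for lists that both favour the starts of active genes. Both lists were called against the same IgG libraries, so part of the excess may come from the shared control, and with peak lists alone this part was not separated.

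The shared regions that ranked high in both lists were at genes of varied function. At SDF2L1 the ERH and WBP11 summits were 170 and 157 bp outside the gene. At EIF2AK3 the WBP11 region, on chromosome 2 at 88627462 to 88627882, had a fold enrichment of 14.6 and a summit 350 bp inside the gene. RBM15 had an ERH region of fold enrichment 40.7 beside its WBP11 region. KHSRP, an RNA-binding splicing regulator, had fold enrichments of 43.3 for ERH and 10.9 for WBP11 on chromosome 19, and OS9, a lectin of endoplasmic reticulum quality control, 27.5 for ERH and 10.5 for WBP11 on chromosome 12. RPS6KA5, a histone kinase, had fold enrichments of 38.2 for ERH and 10.9 for WBP11, and SP1, a transcription factor of GC-rich promoters, 23.5 for ERH and 8.49 for WBP11. MYL11 had a WBP11 region of fold enrichment 11.2.

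Some of the strongest regions of either list had no counterpart in the other. CHAF1A and TOP2A led the ERH gene-end regions without an overlapping WBP11 region, followed by P4HB, a protein disulphide isomerase (fold enrichment 37.6), ILF2 (fold enrichment 25.3), the histone variant gene H3-3B (fold enrichment 31.6) and ETV5, an ETS transcription factor (fold enrichment 39.4). INTS7, LOC124903090, PHF5A, DDX59 and RBBP5 led the WBP11 gene-end regions without an overlapping ERH region, followed by MRPS28, a mitochondrial ribosomal protein (fold enrichment 14.6). INTS7 did have a separate ERH region, with its summit 144 bp outside the same gene. Regions found in both lists were more often at gene ends than the rest of their list: 77.3% against 60.6% for ERH (odds ratio 2.21, Fisher's exact p = 4.05e-14) and 77.8% against 54.3% for WBP11 (odds ratio 2.95, Fisher's exact p = 7.80e-26). ERH-only regions were at gene ends more often than WBP11-only regions (odds ratio 1.30, 95% interval 1.11 to 1.51, two-sided Fisher's exact p = 0.000939).

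Overlap was highest among the strongest regions of each list and did not fall steadily below them. In the strongest decile, 59.6% of ERH regions (interval 52.5 to 66.4) and 53.7% of WBP11 regions (46.6 to 60.8) overlapped the other list, against 30.9% (24.6 to 37.7) and 23.3% (17.6 to 29.7) in the weakest decile. For ERH the share was lowest in decile 7 (22.7%) and higher again in the weakest. The median fold enrichment of shared ERH regions was 11.7, against 9.45 for ERH-only regions (two-sided permutation p = 1.00e-05, the smallest that 100000 resamples can give). This ERH difference of 2.23 fell to 1.29 with a reciprocal overlap of 50% (permutation p = 0.00250) and to 1.07 with summits within 100 bp (permutation p = 0.0159). Shared ERH regions were also wider, with a median of 197 bp against 135 bp, and a wider region meets another by 1 bp more easily. For WBP11 it was 6.41 against 6.11, a difference of 0.304 (two-sided permutation p = 0.00115); with regions of −log10 q of at least 5 alone the difference was 0.0804 (p = 0.670), and with every summit counted 0.0718 (p = 0.0377).

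**Figure D2:**
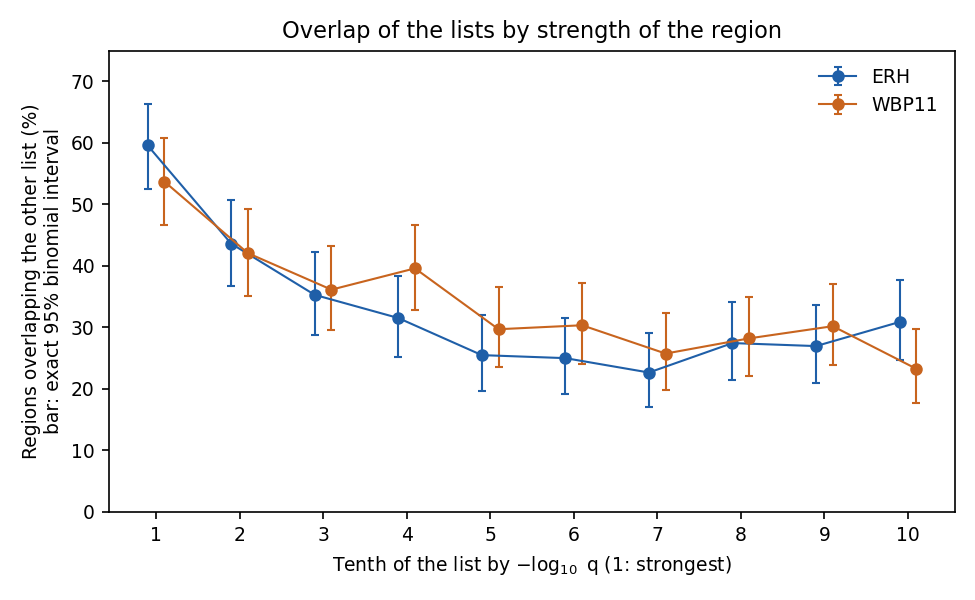
Share of regions that overlap the other list (vertical axis, percent) by decile of each list ordered by −log10 q (horizontal axis, decile 1 the strongest); points are shares and bars exact 95% binomial intervals. The share falls from 59.6% (ERH) and 53.7% (WBP11) in the strongest decile to between 22.7% and 31.5% (ERH) and between 23.3% and 39.6% (WBP11) from decile 4 on.

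Counted by gene, 1614 of 19126 protein-coding genes had an ERH summit within 1000 bp of an end, 1539 had a WBP11 summit and 676 had both, where independent lists would share 130 (odds ratio 13.9, 95% interval 12.3 to 15.7). The 130 assumes that every gene can carry a peak equally, though silent genes such as olfactory receptor genes had none. Activity of the genes was therefore not separated from this odds ratio. ERH alone marked 938 genes and WBP11 alone 863. Both antibodies had peaks at the WBP11 gene itself, on chromosome 12 at 14784582 to 14803478: an ERH region of fold enrichment 9.87 at 14803555 to 14803662 and a WBP11 region of fold enrichment 6.99 at 14803531 to 14803734. The ERH gene, on chromosome 14 at 69380128 to 69398299, had a WBP11 region at 69398294 to 69398403 (fold enrichment 8.40). No ERH region was listed at its ends, the nearest ERH summit being 392185 bp away.

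Genes of cell division carried peaks of both proteins more often than other genes, and histone genes carried ERH peaks. Of 60 genes of mitosis and centromeres, 24 had an ERH peak (odds ratio 7.33, adjusted p = 2.10e-10) and 14 (23.3%) a WBP11 peak (odds ratio 3.50, adjusted p = 0.000766), all by two-sided Fisher's exact tests with Benjamini-Hochberg adjustment over the 40 tests of 20 lists. Of 66 genes of DNA replication and E2F control, 22 had an ERH peak (33.3%, odds ratio 5.49, adjusted exact p = 6.65e-08) and 11 a WBP11 peak (16.7%, odds ratio 2.29, adjusted p = 0.0354). Of 69 replication-dependent histone genes, 30 had an ERH peak (43.5%, odds ratio 8.49, adjusted exact p = 1.09e-13) and 4 a WBP11 peak (5.80%, odds ratio 0.702, adjusted p = 0.693). The WBP11 call for replication genes ended in 4 of the 7 alternatives that change the WBP11 regions or their genes, with an adjusted exact p of up to 0.103. Genes are not replicates, and these tests describe the 2 lists. The other genes in each test of a list include silent ones, such as olfactory receptor genes, which had no peak. No list was matched on gene activity or open chromatin. Activity of the genes in K562 cells was therefore not separated from their function, here or in the lists below.

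In the mitotic list ECT2, a cytokinesis factor, had a fold enrichment of 46.3 for ERH and 8.53 for WBP11. INCENP of the chromosomal passenger complex had 27.3 for ERH and 10.5 for WBP11, and SPC24 of the kinetochore 20.5 for ERH and 6.48 for WBP11. The checkpoint kinase gene TTK had an ERH region alone, with a fold enrichment of 25.9. In the replication list CHAF1A was followed by CDC6, which loads the replicative helicase (fold enrichment 32.8 for ERH), and by the helicase subunit genes MCM3 (23.6 for ERH) and MCM7 (21.7 for ERH and 7.61 for WBP11). Counting the strongest ERH region of each gene, the 30 histone genes stood at 18 distinct regions, since neighbouring histone genes share a region, and 20 ERH regions in all lay within 1000 bp of a histone gene end; 25 of the genes were on chromosome 6 and 5 on chromosome 1. H2AC25 and H2BC26 shared a region on chromosome 1 at 228457827 to 228458108 (fold enrichment 27.8). H2AC4 had a region of fold enrichment 18.2 and H2AC7 of 16.1, both on chromosome 6. Histone genes are near-identical copies, so the assignment of reads to single copies is uncertain. Random lists matched to the histone genes on gene density had a mean of 9.76 genes with an ERH peak, and 30 exceeded all 10000 of them.

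Splicing and DNA damage response genes carried peaks of both proteins more often than other genes. Of 148 splicing genes, 43 had a WBP11 peak (29.1%, odds ratio 4.79, adjusted exact p = 4.59e-13) and 28 an ERH peak (18.9%, odds ratio 2.56, adjusted p = 0.000170). HNRNPC, which packages nascent RNA, had fold enrichments of 47.4 for ERH and 6.23 for WBP11, HNRNPR 32.7 and 4.79, the nuclear speckle gene SON 29.0 and 5.59, and the core small nuclear ribonucleoprotein gene SNRPF 25.3 and 7.30. Of 58 DNA damage response genes, 15 had an ERH peak (odds ratio 3.81, adjusted exact p = 0.000244) and 16 a WBP11 peak (odds ratio 4.39, adjusted p = 4.43e-05). UBE2T, PMS2 and XRCC3 all had both, with ERH fold enrichments of 33.9, 31.5 and 18.6.

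Housekeeping lists were marked more by WBP11 in the single tests, although none of the 4 lists below passed the test between the antibodies; with a fold enrichment of at least 5 the cytosolic ribosomal protein genes did (adjusted exact p = 0.0167). Cytosolic ribosomal protein genes had a WBP11 peak at 19 of 79 (odds ratio 3.65, adjusted exact p = 5.25e-05) and an ERH peak at 8 (adjusted p = 0.620), with RPL34, RPL7 and RPL37 among the WBP11 genes and RPL13 among the ERH genes. Mitochondrial ribosomal protein genes had a WBP11 peak at 14 of 77 (odds ratio 2.55, adjusted exact p = 0.00973) and an ERH peak at 10 (adjusted p = 0.199). MRPS30 had both, MRPS12 had an ERH region alone, and MRPS28 and MRPL1 a WBP11 region alone. Proteasome genes, among them PSMA5 and PSMA3 with both peaks and PSMB3 and PSMD4 with ERH alone, had a WBP11 peak at 10 of 47 (odds ratio 3.10, adjusted exact p = 0.00809) and an ERH peak at 6 (adjusted p = 0.347). Translation factor genes had a WBP11 peak at 12 of 66 (odds ratio 2.55, adjusted exact p = 0.0118) and an ERH peak at 10 (adjusted p = 0.103). EIF2AK3 and EEF1AKMT4 count in that list by symbol although they encode a kinase and a methyltransferase, and each had both peaks. EIF3F also had both peaks, and EIF5 and EIF4A1 an ERH peak alone. The WBP11 call ended in 4 of the same 7 alternatives for proteasome genes (adjusted exact p up to 0.630) and in 3 for translation factor genes (up to 0.790).

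Oxidative phosphorylation genes had an ERH peak at 14 of 86 (odds ratio 2.12, adjusted exact p = 0.0325) and a WBP11 peak at 17 (odds ratio 2.84, adjusted p = 0.00124). Among the complex I genes NDUFB3 and NDUFA6 had both, NDUFS8 had ERH alone, and so had NDUFAF2, which encodes an assembly factor of the complex. Heat shock protein genes had 14 of 62 marked by each protein (odds ratio 3.18, adjusted exact p = 0.00143 for ERH; odds ratio 3.35, adjusted p = 0.00102 for WBP11). HSPA1A and HSPA1L shared an ERH region of fold enrichment 42.2, uncertain because HSPA1A has a near-identical copy, and DNAJB11 and HSP90B1, chaperones of the endoplasmic reticulum, had both peaks. Host genes of small nucleolar RNAs, tested against all 56756 annotated genes, had an ERH peak at 9 of 36 (odds ratio 8.72, adjusted exact p = 2.75e-05) and a WBP11 peak at 6 (odds ratio 5.51, adjusted p = 0.00346); SNHG10, SNHG30, DANCR and TAF1D had both. Small nuclear and polymerase III RNA genes had a WBP11 peak at 5 of 49 (odds ratio 3.13, adjusted exact p = 0.0492), RNU11 and RNU4ATAC of the minor spliceosome among them, and an ERH peak at 3 (adjusted p = 0.505), RNU6-2 and VTRNA1-3 among them. The WBP11 call ended in 4 of the 7 alternatives that change the WBP11 regions or their genes for small nuclear RNA genes (adjusted exact p up to 0.389) and in 2 for small nucleolar RNA host genes (up to 0.0727). With each region assigned to its nearest gene alone, the ERH call for oxidative phosphorylation genes ended (adjusted exact p = 0.250). Their 14 genes with an ERH peak exceeded 97.4% of the density-matched lists, the lowest rank among the higher ERH calls of the lists so matched, and for WBP11 the lowest was that of the replication genes (97.9%).

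Genes of cell identity were not marked beyond other genes. Of 64 erythroid and megakaryocytic genes, the lineages K562 cells resemble, 4 had an ERH peak (6.25%, adjusted exact p = 0.693) and 6 a WBP11 peak (9.38%, adjusted p = 0.693). RHCE, uncertain because of its near-identical copy RHD, and BPGM and PKLR of red cell glycolysis had both, and PPOX of haem synthesis a WBP11 peak alone. None of 38 lymphoid genes (exact 95% interval 0 to 9.25%) and none of 42 liver, brain and muscle genes (0 to 8.41%) had a peak of either protein, with adjusted p of 0.103 and 0.0752 for each antibody. Of 28 myeloid genes, CD68 alone had an ERH peak (adjusted exact p = 0.747) and none had a WBP11 peak (adjusted p = 0.206). None of 389 olfactory receptor genes, silent in most tissues, had a peak (adjusted exact p = 5.73e-14 for ERH and 1.09e-13 for WBP11). Immediate-early genes had an ERH peak at 6 of 36, among them KLF6, SRF, JUND and JUN (adjusted exact p = 0.166), and a WBP11 peak at 2 (adjusted p = 1.00). With a gene-end window of 3000 bp immediate-early genes passed as a list with a higher ERH share (adjusted exact p = 0.00444).

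**Figure D3:**
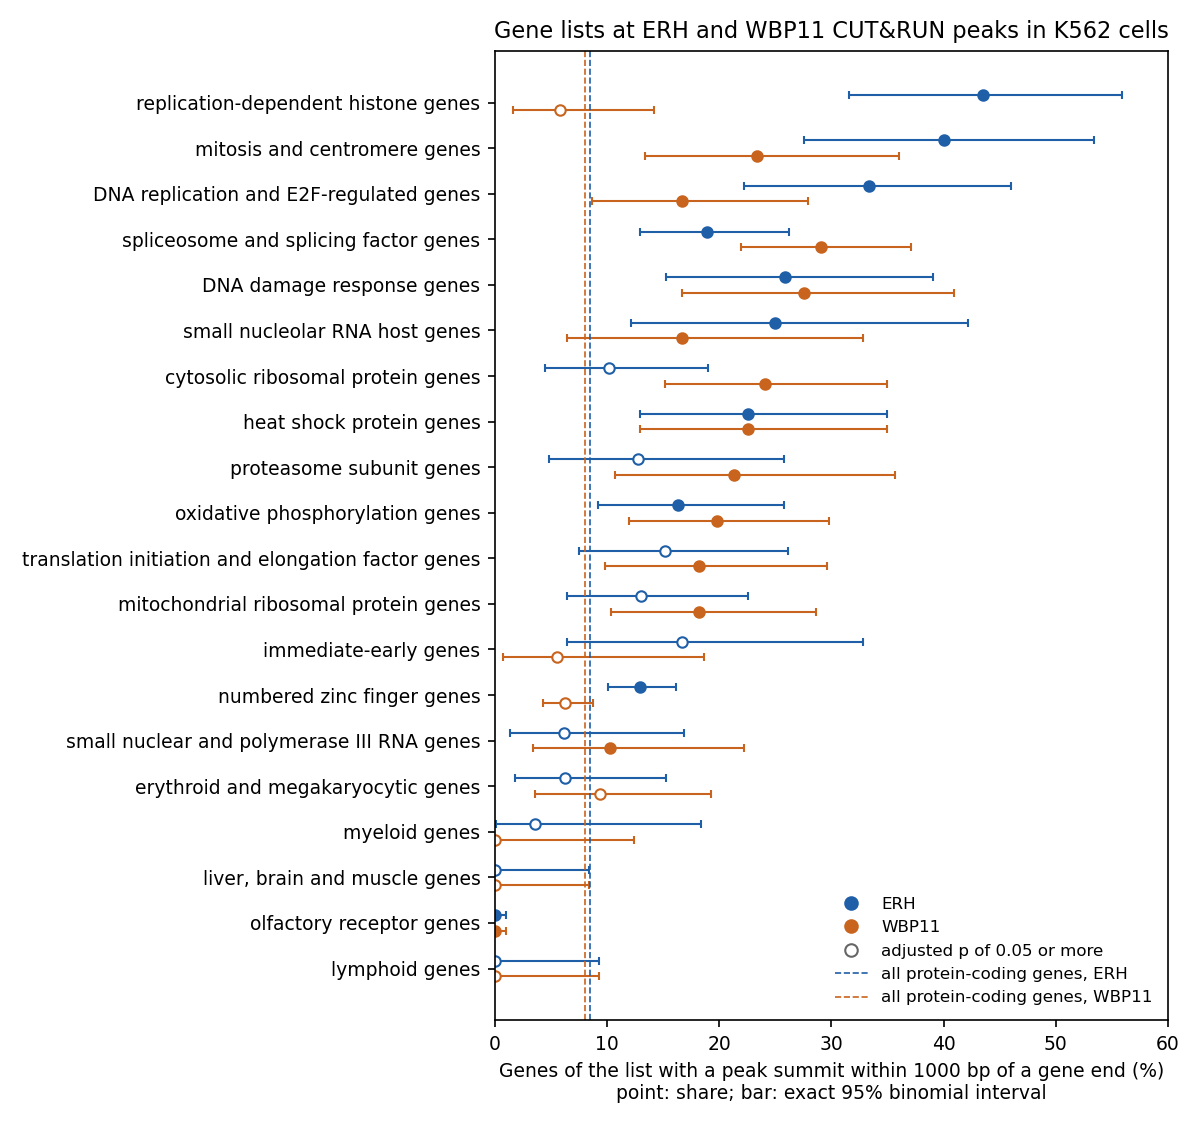
Share of the genes of each list with a peak summit within 1000 bp of a gene end (horizontal axis, percent) for ERH and WBP11; points are shares, bars exact 95% binomial intervals, open points an adjusted p of 0.05 or more, and dashed lines the share among all protein-coding genes, which is not the background of the small nuclear and small nucleolar lists. Histone genes reach 43.5% for ERH and 5.80% for WBP11, and splicing genes 18.9% and 29.1%.

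When genes marked by ERH alone were set against genes marked by WBP11 alone, histone and zinc finger genes leaned to ERH and splicing genes to WBP11. Histone genes counted 28 with ERH alone and 2 with WBP11 alone (odds ratio 13.2, Fisher's exact test adjusted over 20 lists, p = 2.36e-05). With each region assigned to its nearest gene the counts were 18 and 2 (odds ratio 8.21), and the lowest odds ratio among the alternatives was 7.59. Numbered zinc finger genes counted 44 and 11 (odds ratio 3.81, adjusted exact p = 0.000248). Of their 497 members, 64 had an ERH peak (12.9%, odds ratio 1.63, adjusted exact p = 0.00186) and 31 a WBP11 peak (6.24%, adjusted p = 0.200); ZNF8, ZNF92 and ZNF691 had both and ZNF678 had ERH alone. Within chromosome 19 and within the other chromosomes the pooled odds ratio between the antibodies was 2.39 (95% interval 1.20 to 4.76), with 22 against 3 genes on chromosome 19 (odds ratio 1.33, Fisher's exact p = 1.00). With the 1000 strongest regions the ERH call for these genes ended (adjusted exact p = 0.145). Splicing genes counted 11 with ERH alone and 26 with WBP11 alone (odds ratio 0.382, adjusted exact p = 0.0481), a call close to the threshold that ended in 6 of the 8 alternatives that could change it, for example at p = 0.0503 with both lists limited to the length of the shorter. The other 17 lists did not pass this test; the nearest were cytosolic ribosomal protein genes (6 against 17, adjusted exact p = 0.0820) and replication genes (15 against 4, adjusted p = 0.0820). Each passed in 1 alternative, the ribosomal genes with a fold enrichment of at least 5 and the replication genes with each region assigned to its nearest gene (adjusted exact p = 0.0187).

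ERH peaks were concentrated on chromosome 19. There 253 genes (17.4%) had an ERH peak, against 7.70% of genes on the other chromosomes (odds ratio 2.53, 95% interval 2.18 to 2.93, Fisher's exact test adjusted over 44 tests, p = 5.35e-29), and the chromosome held 319 of the 2037 ERH regions. ERH was also higher on chromosome 16 (odds ratio 1.36, adjusted exact p = 0.0271) and lower on chromosomes 4, 5, 8, 10, 13, 15 and 18, with odds ratios from 0.371 to 0.625. For WBP11 the share was higher on chromosome 1 (11.3%, odds ratio 1.55, adjusted exact p = 6.29e-07) and chromosome 6 (odds ratio 1.36, adjusted p = 0.0166), and lower on chromosomes 9, 10, 17 and 18, with odds ratios from 0.346 to 0.738. With a fold enrichment of at least 5, 1 chromosome in place of 6 differed for WBP11. Copy number in K562 cells and activity of the genes were not measured. Neither was separated from these shares, and copy number is taken up below for chromosome 19 alone. On chromosome 19 WBP11 marked 8.34% of genes (odds ratio 1.04, adjusted exact p = 0.819). Among genes marked by a single protein, chromosome 19 counted 160 with ERH alone and 28 with WBP11 alone (odds ratio 6.13, 95% interval 4.03 to 9.63, Fisher's exact test adjusted over 22 chromosomes, p = 3.05e-22); with a fold enrichment of at least 5 the odds ratio was 3.64. Chromosomes 16 and 17 also leaned to ERH (odds ratios 2.40 and 2.00), and chromosomes 1, 4, 5 and 15 to WBP11 (odds ratios 0.562, 0.316, 0.470 and 0.437).

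**Figure D4:**
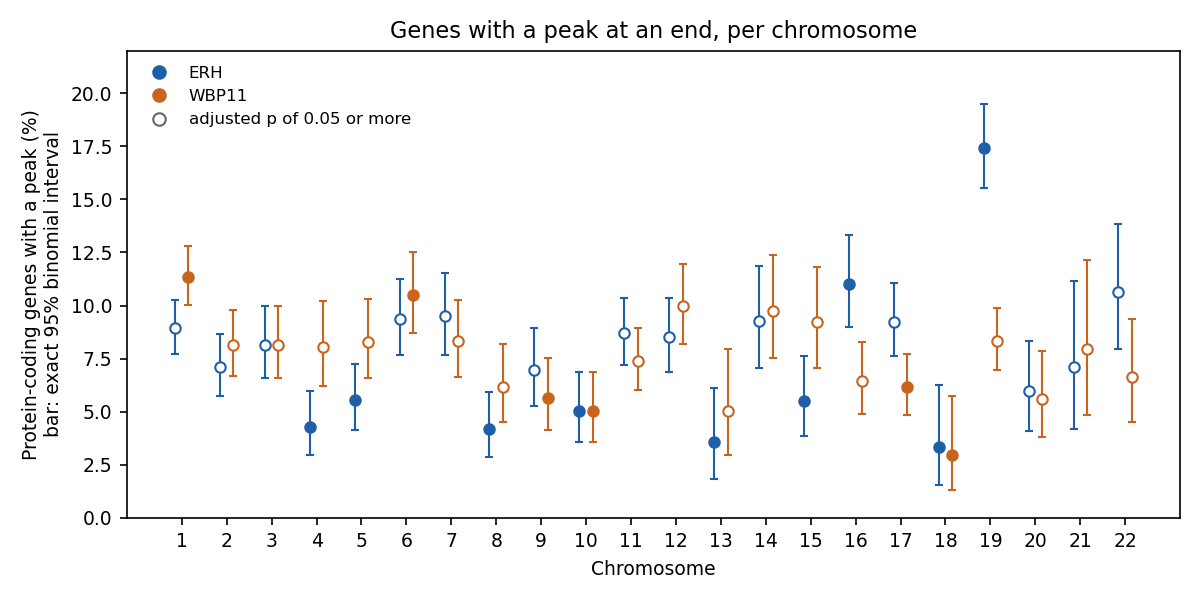
Share of the protein-coding genes of each chromosome (horizontal axis) with a peak summit within 1000 bp of a gene end (vertical axis, percent); points are shares, bars exact 95% binomial intervals and open points an adjusted p of 0.05 or more. For ERH chromosome 19 stands at 17.4% above every other chromosome, and for WBP11 chromosome 1 is highest at 11.3%.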

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

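The tests of causes given below for histone genes, zinc finger genes, chromosome 19 and the overlap were chosen only after these patterns had been seen, and for the comparison at equal ERH strength and for copy number the values that decide them were partly known. Among 20 gene lists and 22 chromosomes, 10 differed between genes marked by ERH alone and genes marked by WBP11 alone. The odds ratio, above 1 toward ERH, was 13.2 for histone genes, 0.382 for splicing genes and 3.81 for numbered zinc finger genes. By chromosome it was 0.562 on chromosome 1, 0.316 on chromosome 4, 0.470 on chromosome 5 and 0.437 on chromosome 15, and 2.40 on chromosome 16, 2.00 on chromosome 17 and 6.13 on chromosome 19.

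Histone genes had ERH peaks at 30 and WBP11 peaks at 4 of 69 genes. Stronger enrichment in the ERH list is not the whole cause, since 1 of 20 ERH regions within 1000 bp of a histone gene end overlapped a WBP11 region, against a mean of 8.32 in 10000 draws of other ERH gene-end regions of the same decile of −log10 q (one-sided permutation p = 0.000300). Neighbouring genes sharing a region are not the whole cause either. With each region counted for its nearest gene only, 18 against 2 genes remained (Fisher's exact p = 0.000520). Of the 20 summits, 17 lay outside the histone genes (85%, lower 95% bound 62.1%), close to the 86.6% of all ERH gene-end summits. This comparison therefore cannot decide whether near-identical coding sequences contribute. Open remain near-identical coding sequences, duplicated sequence beside the genes and base composition, which were not tested for lack of sequence. As a hypothesis, a difference in where the 2 proteins sit in dividing cells may also underlie the pattern.

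Chromosome 19 held ERH peaks at 17.4% of its genes. Its density of genes is not the whole cause, because within deciles of gene density the pooled odds ratio was 1.91 with a lower 95% bound of 1.63, nor are its zinc finger genes, without which the odds ratio was 2.77 with a lower bound of 2.36. Copy number or mappability common to all libraries would raise WBP11 too, but its odds ratio had an upper bound of 1.27, below the 2.18 of ERH. Conversely, the excess of zinc finger genes toward ERH fell from 3.81 to a pooled odds ratio of 2.39 (lower bound 1.20) over 2 strata: 1.33 (0.357 to 7.44, Fisher's exact p = 1.00) on chromosome 19, whose interval includes 1, and 3.01 (1.28 to 7.86, p = 0.00560) on the other chromosomes, so the chromosome may carry part of it. The high GC content of chromosome 19 could act differently on libraries of different antibodies and was not tested, and a biological preference of ERH stays open as untested.

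The overlap of the lists was not due to annotated gene ends alone: more than 1000 bp from the end of any annotated gene, 21.2% of ERH regions (111 of 524) overlapped a WBP11 region, against at most 0.382% in local random placements. The annotation gives a single start and end per gene, so shared use of further transcription starts inside genes was not excluded. The overlap was not confined to a few chromosomes, since it exceeded every local placement on 22 of 22. On chromosomes 13 and 18 this rested on 3 shared ERH regions each. Neither copy number nor repeats were measured, so amplified or repetitive stretches spread over the chromosomes were not excluded. Regions without a counterpart were not simply weak ERH regions, as 40.4% of the strongest decile of ERH regions lacked one, although WBP11 signal just under its own threshold remains possible. Nuclease cutting at open chromatin by any antibody and the IgG control common to both lists could each produce common regions, and neither was tested; a joint presence of the proteins is therefore a hypothesis only.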

How the results depend on the processing

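Every-summit counting, local placement, assignment to the nearest gene and the 1000 strongest regions were chosen only after the data were seen. Among the recomputed main results, 194 stayed on their side of the threshold, or within 1.5 times for a count, 7 counts moved further and 1 result fell short of the threshold. None of the results past their threshold changed direction; some odds ratios that had not passed crossed 1, such as that of translation factor genes between the antibodies (0.688, up to 1.84). These totals include the settings named below that change nothing by construction. The share of regions at gene ends ranged from 61.9% to 74.3% for ERH and from 58.0% to 68.4% for WBP11, and the overlap from 21.7% to 36.8% of ERH regions. The odds ratio of marking the same genes ranged from 11.9 to 15.0. With −log10 q of at least 5 there were 1122 WBP11 regions, 7 lists with a higher WBP11 share in place of 12, 2 with a lower share in place of 1 (numbered zinc finger genes joined), and a WBP11 difference in median fold enrichment between shared and specific regions of 0.0804 (permutation p = 0.670). The first follows from the fewer regions; for the others the cause was not tested. Lists with a lower share also numbered 2 for WBP11 with the 1000 strongest regions, and 2 for ERH and 2 for WBP11 with a gene-end window of 3000 bp, where lymphoid genes (ERH) and liver, brain and muscle genes (WBP11) joined at adjusted exact p = 0.0499 each. With a fold enrichment of at least 5, 1 chromosome differed for WBP11; the cause was not tested.

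For single lists and chromosome 19, 635 recomputed odds ratios stayed on their side of the threshold, 25 fell short of it and 7 passed it. Between the antibodies, histone genes kept an adjusted exact p of at most 0.00755 and zinc finger genes of at most 0.0123 over 11 alternatives, while splicing genes ranged from 0.0241 to 0.182 and ended in 6; 3 of the 11 change nothing by construction. Leaving out replicate 1 or replicate 2 changed nothing by construction, and restriction to chromosomes 1 to 22 and X removed no region, so neither says anything about stability. No paired analysis was possible because the 2 replicate lists of each antibody were identical. Not run, for lack of strand, exons or sequence, were the alternatives on motifs and their flanks, CpG thresholds and CpG-rich backgrounds, exon boundary windows, soft-masked repeats and opposite-strand promoters. Depth is unknown, and a gene without a listed peak was not shown to be free of the protein.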

Other observations

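The list of unfolded protein response genes used here, its test and the count of transfer RNA genes were chosen only after the strongest shared regions had been seen. Those regions included SDF2L1, EIF2AK3 and OS9, which act in the endoplasmic reticulum, and HSPA5, HSP90B1, DNAJB11 and P4HB had been noticed with them. Of 34 genes written down as members of this response, 22 (64.7%) had an ERH peak, 15 (44.1%) a WBP11 peak and 13 (38.2%) both, against 8.34%, 7.98% and 3.47% of the other protein-coding genes. It was the only list written this way, and DNAJB9, DNAJC3, HSPA5, HSP90B1 and DNAJB11 also belong to the heat shock list of the main comparison. Because 7 members had prompted the list, the hypothesis that both proteins sit at these genes as a group was tested on the other 27. DNAJB9 and DNAJC3 of the heat shock list, already tested above, remained among these 27. Of these, 15 had an ERH peak (odds ratio 13.7, 95% interval 5.99 to 32.2), 9 a WBP11 peak (odds ratio 5.76, interval 2.28 to 13.5) and 7 both (odds ratio 9.73, lower bound 3.46, two-sided Fisher's exact p = 3.03e-05, adjusted over these 3 tests p = 4.54e-05). The result is consistent with a feature of the group, as a hypothesis; whether a shared promoter element or high activity of these genes in K562 cells underlies it was not tested.

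Among the members not noticed first, SEL1L of the degradation pathway of the endoplasmic reticulum had an ERH region on chromosome 14 at 81533846 to 81534140 (fold enrichment 32.0) and a WBP11 region of fold enrichment 7.64. The secreted factor gene MANF on chromosome 3 had fold enrichments of 26.9 for ERH and 6.95 for WBP11, and PDIA4, a disulphide isomerase, 22.3 for ERH and 6.71 for WBP11. DNAJC3, HERPUD1, CALR and DNAJB9 also had both, with WBP11 −log10 q values of 2.98, 3.31, 5.01 and 10.4, against a lowest listed value of 2.02. At DNAJB9 the ERH and WBP11 regions did not overlap. The test of this gene group was not recomputed under stricter thresholds. DERL3 (fold enrichment 39.5), DERL2 (19.2), HYOU1 (13.8), DDIT3 (11.1), CRELD2 (8.63), EDEM1 (7.32), XBP1 (6.78) and ATF4 (5.70) had an ERH region alone, and CANX (8.65) and SEC61B (6.24) a WBP11 region alone. These names were chosen after their values were seen.

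Of 439 transfer RNA genes, 7 had an ERH summit and 9 a WBP11 summit within 500 bp, a count set against no background.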
